A study of Rattus norvegicus with 12 samples.

How the data were processed

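The series holds RNA sequencing of rat brain in 12 libraries. Per the labels, total RNA was extracted with Trizol and had an RNA integrity number above 8. The submitters' processing notes name HISAT2, without a version, and the genome Rnor_6.0. The counting program, the annotation and the strandedness are not given in the sources used here, nor are the dissected region and the time after the stroke. The deposited table holds unscaled gene counts, 37209 gene symbols by 12 libraries, all in whole numbers. Of the symbols, 20212 match a current rat gene name and 2844 a synonym, on a newer assembly used for names only, and 14153 match neither. Of the column codes, 11 match a sample title, and 1 MCAO column does not. Sham LN was matched to MCAO and sham PN to pontine infarction by the first letter of their codes.

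Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 17008 genes, 45.7% of the symbols. A quasi-likelihood model with TMM scaling was fitted to all 12 libraries, and the common biological coefficient of variation was 0.302. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, and all tests are two-sided. SE is the absolute log2 change over the square root of F. A prior count of 2 entered library log2 values, not log2 changes. The 4 comparisons were MCAO with sham LN, pontine infarction with sham PN, the difference between these responses, and sham LN with sham PN. Of 44 gene lists written before the data were examined, 41 with at least 5 tested members were tested by camera with a preset correlation of 0.01, and beside it by camera with an estimated correlation and by fry. The red cell and pituitary lists were too short, and sex-linked genes were not tested. List tests of the difference and of the shams were added later.

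Named genes were picked by a rule: the 8 largest changes in each direction (5 between shams and for the difference) with an adjusted p under 0.05, at least 5 CPM in the higher group and groups that do not overlap. To these came up to 3 examples per list and the fixed genes Gfap, Aif1, Cd68, Spp1, Hmox1, Fos, Snap25, Slc17a7, Mbp and Cldn5. Against a group at 0 counts a fold is given against a floor of 3 counts over the group. Libraries held 19805815 to 40400676 counts. On simulated counts with 200 genes changed, changes of 2-fold were called for 31.3% of genes in the design of MCAO, 28.4% for pontine infarction, 35.8% for the shams and 8.96% for the difference. At 4-fold these shares were 86.6%, 82.1%, 86.6% and 55.2%, and at 8-fold 97.0%, 97.0%, 90.9% and 90.9%. False calls were 6 of 149, 6 of 144, 6 of 148 and 1 of 104. Of 41 simulated lists the 1 shifted list was called and 0 others were. Wrong splits of the real MCAO libraries called 7 to 29 lists, so the simulation does not bound false list calls.

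The alternatives were DESeq2 size factors, no filter, a filter of 1 CPM in 3 libraries, DESeq2, limma voom, a fit on the compared libraries alone, the replicate number as a block, a 2-fold minimum, all 6 shams as one control, and leaving out each library in turn.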

Results

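Brain RNA was sequenced from Sprague Dawley rats at postnatal day 21 in 12 libraries of 4 groups with 3 libraries each. The groups were stroke by middle cerebral artery occlusion (MCAO, the blocking of the main artery of the cerebral hemisphere), pontine infarction (a stroke of the pons, the middle part of the brainstem) and a pair of sham groups coded LN and PN. Sham LN was compared with MCAO and sham PN with pontine infarction, because their codes share a first letter. The labels name only brain as the tissue and give neither the dissected region nor the time after the stroke. The labels mention 3 rats for each stroke, and the p-values given here measure the spread between samples. One MCAO library, whose column code has a number found in no sample title, is called the unnumbered MCAO library. The samples, comparisons, alternatives, gene lists and the rule for naming genes were chosen before the data were examined, except where stated.

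The libraries held 19958472, 20408615 and 21476777 counts in MCAO replicates 1 and 2 and the unnumbered library, and 40400676, 29521806 and 27286982 in sham LN replicates 1 to 3. Pontine infarction replicates 1 to 3 had 19805815, 38722682 and 24417059 counts, and sham PN replicates 1 to 3 had 22766142, 27215062 and 29905241. Of 37209 gene symbols, 17008 had enough counts to be tested, and the others held 0.0453% of the counts. Levels are normalised counts (CPM) as mean ± SD of the 3 libraries of a group, and log2 changes are given ± SE. Counting intervals and floors cover counting error only. Where the members of a list are counted in a single direction, none passed in the other. Mitochondrial transcripts made up 4.56 ± 0.337% of the counts after MCAO, 5.12 ± 0.413% in sham LN, 4.70 ± 0.843% after pontine infarction and 4.77 ± 0.326% in sham PN.

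MCAO was compared with sham LN to see which transcripts differ in the brain after this stroke. Gfap, the intermediate filament of astrocytes, rose from a sham mean of 434 ± 70.7 CPM to 3594 ± 219 CPM (log2 change 3.05 ± 0.22, edgeR adjusted p = 7.24e-05). Itgax, an integrin of dendritic cells and activated microglia, stood at 16.9 ± 5.43 CPM against 0.115 ± 0.0665 in shams (log2 change 7.09 ± 0.44, edgeR adjusted p = 5.2e-05), and Spp1, which encodes the secreted protein osteopontin, at 165 ± 129.7 CPM against 0.713 ± 0.225 in shams (log2 change 7.83 ± 0.81, edgeR adjusted p = 0.000821). Cxcl3, a chemokine that attracts neutrophils, had 3699 counts over the MCAO libraries and 0 over the shams, so it was at least 1820-fold higher against a floor of 3 counts over the group. Mal, a protein of myelin membranes, fell to 169 ± 24.0 CPM from 473 ± 55.6 (log2 change -1.49 ± 0.18, edgeR adjusted p = 0.00144).

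In all, 3163 genes changed after MCAO, 18.6% of those tested, of which 2131 rose and 1032 fell (edgeR quasi-likelihood test). At least 2-fold changes numbered 1673 upward and 476 downward. The count depended on single libraries. It was 1426 without MCAO replicate 1, 6170 (2873 rose, 3297 fell) without MCAO replicate 2 and 1517 without the unnumbered MCAO library. It was 1136, 1544 and 1257 without sham LN replicates 1 to 3. Fitted on the 6 compared libraries alone it was 1354 (1125 rose, 229 fell). DESeq2 called 4584 (2532 rose, 2052 fell) and limma voom 5390 (3038 rose, 2352 fell). Of 120 genes named by the rule that passed, 81 stayed past the threshold whichever of the 6 libraries was left out, among them Gfap, Itgax, Spp1, Cxcl3 and Mal. On the compared libraries alone 30 lost the threshold. With 1 library left out log2 changes ran from 2.90 to 3.17 for Gfap, 6.73 to 7.42 for Itgax, 6.97 to 8.09 for Spp1 and -1.61 to -1.40 for Mal. By camera with its preset correlation 28 of 41 gene lists passed, 20 upward and 8 downward, and by fry 27, and in each of the 28 all 3 MCAO libraries had medians on the list's side. With an estimated correlation none did by camera, and the adjusted p-values of the 28 lists then lay between 0.175 and 0.535.

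Neutrophil and monocyte markers and cytokines had the highest median changes of the tested lists after MCAO. Of 23 cytokine and chemokine genes, 20 rose and 3 did not pass (22 rose adjusted over the list alone), at a median log2 change of 7.11 (camera adjusted p = 5.75e-17, adjusted p = 0.214 by estimated correlation). Ccl3, a chemokine that draws monocytes, stood at 156 ± 141 CPM against 0.0878 ± 0.152 in shams (log2 change 10.46 ± 1.47, edgeR adjusted p = 0.00229). Cxcl2 and Ccl7, chemokines for neutrophils and monocytes, had 1 count each over the shams, which gives 13449-fold and 11293-fold (95% counting intervals 2413 to 531255 and 2026 to 446093). Neutrophil and monocyte markers had a median log2 change of 7.24 (camera adjusted p = 4.21e-12, adjusted p = 0.214 by estimated correlation). Of 12 members 12 rose (12 rose adjusted over the list alone). Members need enough counts (12 of 20 listed here, 8 of 20 for lymphocytes), which favours genes that rose from near 0. Csf3r, the receptor for the neutrophil growth factor G-CSF, stood at 124 ± 80.2 CPM against 3.71 ± 0.497 in shams (log2 change 5.06 ± 0.65, edgeR adjusted p = 0.00162). Slpi, a neutrophil protease inhibitor, had 1 count over the shams (12394-fold, 95% counting interval 2224 to 489578). Phagocyte activation genes had a median log2 change of 3.94 (camera adjusted p = 4.24e-18, adjusted p = 0.214 by estimated correlation), and of 23 members 17 rose and 6 did not pass (17 rose and 1 fell adjusted over the list alone). Clec7a, a receptor for fungal glucans found on activated microglia, stood at 23.8 ± 8.28 CPM against 0.0466 ± 0.0264 in shams (log2 change 8.93 ± 0.88, edgeR adjusted p = 0.000679), and Cd68, a lysosomal protein of macrophages, rose with a log2 change of 5.52 ± 0.99. Of 17 complement genes, 11 rose and 6 did not pass (12 rose adjusted over the list alone), at a median log2 change of 2.60 (camera adjusted p = 3.54e-08, adjusted p = 0.218 by estimated correlation). Itgam, a subunit of complement receptor 3, rose with a log2 change of 4.26 ± 0.45 (edgeR adjusted p = 0.00084).

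MCAO replicate 2 stood closer to the shams in each of these groups. Its median log2 difference from the sham mean was 3.91 for neutrophil and monocyte markers, against 7.70 in replicate 1 and 6.64 in the unnumbered library. The same medians for phagocyte activation genes were 4.91 in replicate 1, 1.92 in replicate 2 and 3.34 in the unnumbered library. The red cell genes Hba1 and Hba2, which mark blood in the tissue, summed to 77.8 ± 17.6 CPM after MCAO and 57.7 ± 43.4 CPM in sham LN. Markers of resting microglia had a median log2 change of -0.23 (camera adjusted p = 0.385). Of 14 members 1 rose, 1 fell and 12 did not pass (2 rose and 2 fell adjusted over the list alone). Gpr84, a fatty acid receptor induced in activated myeloid cells, rose (log2 change 2.51 ± 0.43), and Tmem119, a membrane protein of resting microglia, fell (log2 change -1.84 ± 0.58, edgeR adjusted p = 0.0473). Tmem119 did not pass when MCAO replicate 1, the unnumbered MCAO library and sham LN replicates 1, 2 and 3 were each left out (adjusted p = 0.129, 0.142, 0.107, 0.1 and 0.0998). Aif1, the microglial and macrophage protein Iba1, stood at 17.1 ± 10.3 CPM against 7.21 ± 1.04 in shams and did not pass (log2 change 1.24 ± 0.42, edgeR adjusted p = 0.0591). Of 8 lymphocyte markers, 4 rose, 1 fell and 3 did not pass (4 rose and 1 fell adjusted over the list alone), at a median log2 change of 3.39 (camera adjusted p = 0.0418, adjusted p = 0.323 by estimated correlation). Cd2, a T cell adhesion protein, had 3 counts over the shams and 157 over the MCAO libraries (77-fold, 95% counting interval 26 to 379).

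Host defence lists passed upward by camera as well. Of 24 interferon-stimulated genes, 17 rose and 7 did not pass (20 rose adjusted over the list alone), at a median log2 change of 2.12 (camera adjusted p = 4.52e-11, adjusted p = 0.266 by estimated correlation). Ifit3, an interferon-induced inhibitor of viral RNA translation, stood at 73.9 ± 36.9 CPM against 1.199 ± 0.448 in shams (log2 change 5.92 ± 0.83, edgeR adjusted p = 0.00225). Antigen presentation genes had a median log2 change of 3.29 (camera adjusted p = 1.78e-09, adjusted p = 0.245 by estimated correlation). Of 18 members 14 rose and 4 did not pass (16 rose adjusted over the list alone). Cd74, the invariant chain of MHC class II, stood at 95.1 ± 69.9 CPM against 4.15 ± 0.179 in shams (log2 change 4.52 ± 0.71, edgeR adjusted p = 0.00303). Cell death and p53 target genes had a median log2 change of 1.95 (camera adjusted p = 9.81e-12, adjusted p = 0.218 by estimated correlation), and of 23 members 15 rose and 8 did not pass (20 rose adjusted over the list alone). Of 17 vessel activation and sprouting genes, 11 rose and 6 did not pass (13 rose adjusted over the list alone), at a median log2 change of 3.54 (camera adjusted p = 2.34e-07, adjusted p = 0.245 by estimated correlation). Icam1, an adhesion protein that captures leukocytes, rose (log2 change 4.84 ± 0.80, edgeR adjusted p = 0.00368).

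Astrocyte genes split by function after MCAO. Reactive astrocyte genes had a median log2 change of 4.61 (camera adjusted p = 3.46e-25, adjusted p = 0.175 by estimated correlation). Of 22 members 21 rose and 1 did not pass (21 rose adjusted over the list alone). Aspg, an asparaginase, stood at 10.5 ± 1.44 CPM against 0.0933 ± 0.0528 in shams (log2 change 6.81 ± 0.46, edgeR adjusted p = 5.37e-05), and Cd44, a hyaluronan receptor, rose with a log2 change of 5.03 ± 0.56. Of 18 general astrocyte markers, 10 fell and 8 did not pass (11 fell adjusted over the list alone), at a median log2 change of -0.76 (camera adjusted p = 4.52e-08, adjusted p = 0.245 by estimated correlation). Gja1 and Gjb6, the connexins that couple astrocytes, fell with log2 changes of -1.14 ± 0.18 and -2.40 ± 0.48 (edgeR adjusted p = 0.00304 and 0.00796). Matrix and fibroblast genes had a median log2 change of 1.496 (camera adjusted p = 2.74e-07, adjusted p = 0.246 by estimated correlation), and of 22 members 10 rose and 12 did not pass (14 rose adjusted over the list alone). Mmp14, a membrane-bound matrix protease, and Fn1, fibronectin, rose with log2 changes of 3.68 ± 0.54 and 2.44 ± 0.38. Of 20 axon growth inhibitor genes, 2 rose, 2 fell and 16 did not pass (2 rose and 3 fell adjusted over the list alone), at a median log2 change of -0.49 (camera adjusted p = 0.0418, adjusted p = 0.405 by estimated correlation). Without MCAO replicate 1 this list's camera adjusted p was 0.178, and without sham LN replicate 2 it was 0.0836. Ncan, the proteoglycan neurocan, rose (log2 change 2.07 ± 0.25, edgeR adjusted p = 0.00137). Reactive astrocyte medians were 5.13 in replicate 1, 2.74 in replicate 2 and 4.57 in the unnumbered library.

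Vessel wall lists did not pass after MCAO, although single members did. Endothelial and barrier genes had a median log2 change of 0.05 (camera adjusted p = 0.973). Of 20 members 2 rose and 18 did not pass (2 rose adjusted over the list alone). The mean log2 change of this list was negative, at -0.01. Cldn5, the main claudin of the blood-brain barrier, stood at 82.4 ± 36.2 CPM against 139 ± 16.8 in shams (edgeR adjusted p = 0.109). Of 15 mural cell markers, 4 rose, 1 fell and 10 did not pass (4 rose and 1 fell adjusted over the list alone), at a median log2 change of 0.13 (camera adjusted p = 0.454). Anpep, an aminopeptidase of pericytes and myeloid cells, rose with a log2 change of 4.10 ± 0.62, and Des, the muscle filament desmin, with 1.99 ± 0.33.

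Stress lists passed upward by camera after MCAO, with 7 to 11 members of each not past the threshold. Of 17 heat shock and chaperone genes, 10 rose and 7 did not pass (15 rose adjusted over the list alone), at a median log2 change of 0.94 (camera adjusted p = 4.78e-10, adjusted p = 0.214 by estimated correlation). Hspb1, the small heat shock protein HSP27, stood at 405 ± 162 CPM against 4.31 ± 0.452 in shams (log2 change 6.55 ± 0.72, edgeR adjusted p = 0.000909). Immediate early genes had a median log2 change of 1.45 (camera adjusted p = 0.000147, adjusted p = 0.295 by estimated correlation). Of 20 members 10 rose and 10 did not pass (11 rose adjusted over the list alone). Atf3, a stress-induced transcription factor, stood at 27.9 ± 19.9 CPM against 0.330 ± 0.252 in shams (log2 change 6.32 ± 0.78, edgeR adjusted p = 0.00146), and Fos, a marker of recent neuronal activity, rose (log2 change 2.96 ± 0.69, edgeR adjusted p = 0.0154). Fos did not pass when sham LN replicates 1, 2 and 3 were each left out (adjusted p = 0.0623, 0.0507 and 0.0653). Regeneration-associated genes had a median log2 change of 1.61 (camera adjusted p = 5.78e-07, adjusted p = 0.214 by estimated correlation), and of 22 members 11 rose, 1 fell and 10 did not pass (14 rose and 2 fell adjusted over the list alone). Tubb6, a tubulin of regrowing axons and other cells, rose with a log2 change of 5.17 ± 0.49. Of 21 hypoxia and glycolysis genes, 10 rose and 11 did not pass (12 rose adjusted over the list alone), at a median log2 change of 0.61 (camera adjusted p = 6.04e-06, adjusted p = 0.266 by estimated correlation). Hk2, a hexokinase, rose with a log2 change of 2.57 ± 0.38. Unfolded protein response genes had a median log2 change of 0.61 (camera adjusted p = 1.35e-06, adjusted p = 0.266 by estimated correlation). Of 20 members 9 rose and 11 did not pass (14 rose adjusted over the list alone).

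Iron and redox lists passed upward by camera. Of 20 iron handling genes, 9 rose and 11 did not pass (10 rose adjusted over the list alone), at a median log2 change of 0.70 (camera adjusted p = 0.000434, adjusted p = 0.266 by estimated correlation). Hmox1, the heme-degrading enzyme heme oxygenase 1, stood at 332 ± 279.5 CPM against 5.80 ± 0.212 in shams (log2 change 5.83 ± 0.70, edgeR adjusted p = 0.00134). Oxidative stress genes had a median log2 change of 0.90 (camera adjusted p = 0.00491, adjusted p = 0.34 by estimated correlation). Of 18 members 8 rose, 2 fell and 8 did not pass (11 rose and 3 fell adjusted over the list alone). Nuclear-encoded respiratory chain genes had a median log2 change of -0.06 (camera adjusted p = 0.184), and of 23 members 1 fell and 22 did not pass (none passed adjusted over the list alone). Mitochondrially encoded genes had a median log2 change of -0.21 (camera adjusted p = 0.104), and 0 of 13 passed, also when adjusted over the list alone. Without the unnumbered MCAO library the mitochondrial list had a camera adjusted p of 0.03.

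Neuronal lists leaned downward after MCAO, with 0 to 8 members past the threshold. Of 15 striatal projection neuron markers, 8 fell and 7 did not pass (9 fell adjusted over the list alone), at a median log2 change of -1.201 (camera adjusted p = 1.35e-06, adjusted p = 0.266 by estimated correlation). Adcy5, the main adenylyl cyclase of striatal neurons, stood at 535 ± 224 CPM against 1229 ± 342 in shams (log2 change -1.201 ± 0.28, edgeR adjusted p = 0.0152). Adcy5 did not pass when the unnumbered MCAO library and sham LN replicates 1 and 3 were each left out (adjusted p = 0.0652, 0.0663 and 0.0559). Synaptic genes had a median log2 change of -0.59 (camera adjusted p = 3.84e-05, adjusted p = 0.364 by estimated correlation). Of 21 members 3 fell and 18 did not pass (4 fell adjusted over the list alone). Snap25, a protein of synaptic vesicle fusion, stood at 1131 ± 199.9 CPM against 1377 ± 147 in shams and did not pass (edgeR adjusted p = 0.384). Excitatory neuron markers had a median log2 change of -0.46 (camera adjusted p = 0.00972, adjusted p = 0.405 by estimated correlation), and 0 of 18 passed, also when adjusted over the list alone. The camera adjusted p of this list was 0.178 without MCAO replicate 1 and 0.0774 without sham LN replicate 2. Slc17a7, the vesicular glutamate transporter of cortical neurons, stood at 952 ± 478 CPM against 1123 ± 431 in shams (edgeR adjusted p = 0.852). Of 15 inhibitory neuron markers, 1 fell and 14 did not pass (1 fell adjusted over the list alone), at a median log2 change of -0.41 (camera adjusted p = 0.0616). That camera adjusted p was 0.0263 without the unnumbered MCAO library. The striatal medians were -1.68 in replicate 1, -0.50 in replicate 2 and -1.65 in the unnumbered library.

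Regional genes followed no single direction after MCAO. Of 13 telencephalon genes, 1 fell and 12 did not pass (none passed adjusted over the list alone), at a median log2 change of -0.59 (camera adjusted p = 0.0309, adjusted p = 0.419 by estimated correlation). The camera adjusted p was 0.202 without MCAO replicate 1 and 0.0747 without sham LN replicate 2. Hindbrain genes had a median log2 change of 0.26 (camera adjusted p = 0.211). Of 22 members 4 rose and 18 did not pass (4 rose adjusted over the list alone). Slc6a5, the glycine transporter of hindbrain inhibitory neurons, stood at 14.1 ± 9.42 CPM against 2.42 ± 0.524 in shams (log2 change 2.54 ± 0.61, edgeR adjusted p = 0.0166). Slc6a5 did not pass when MCAO replicate 1, the unnumbered MCAO library and sham LN replicates 1, 2 and 3 were each left out (adjusted p = 0.0586, 0.0657, 0.0727, 0.0604 and 0.0509). Cerebellar markers had a median log2 change of -0.55 (camera adjusted p = 0.517), and of 16 members 2 rose and 14 did not pass (1 rose adjusted over the list alone). The mean log2 change of cerebellar markers was positive, at 0.37.

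Oligodendrocyte lists passed downward by camera after MCAO, and some members did not pass. Of 17 myelin and oligodendrocyte genes, 11 fell and 6 did not pass (15 fell adjusted over the list alone), at a median log2 change of -1.05 (camera adjusted p = 2.82e-12, adjusted p = 0.175 by estimated correlation). Fa2h and Ugt8, enzymes that make myelin galactolipids, fell with log2 changes of -1.24 ± 0.18 and -1.05 ± 0.16 (edgeR adjusted p = 0.00244 and 0.0029). Mbp, myelin basic protein, stood at 7228 ± 1787 CPM against 12009 ± 2644 in shams and did not pass (log2 change -0.73 ± 0.24, edgeR adjusted p = 0.0528). The myelin medians were -0.95 in replicate 1, -1.11 in replicate 2 and -0.89 in the unnumbered library. Oligodendrocyte precursor genes had a median log2 change of -0.47 (camera adjusted p = 0.000431, adjusted p = 0.214 by estimated correlation). Of 16 members 5 fell and 11 did not pass (5 fell adjusted over the list alone). Cholesterol synthesis genes had a median log2 change of -0.12 (camera adjusted p = 0.0749), and of 19 members 3 fell and 16 did not pass (3 fell adjusted over the list alone). The cholesterol median was -0.28 without the unnumbered MCAO library (camera adjusted p = 0.00191) and -0.17 without sham LN replicate 3 (camera adjusted p = 0.0433). Of 14 sterol efflux genes, 6 rose and 8 did not pass (6 rose and 1 fell adjusted over the list alone), at a median log2 change of 0.38 (camera adjusted p = 0.0599). The sterol efflux median was 0.48 without the unnumbered MCAO library (camera adjusted p = 0.0242) and 0.40 without sham LN replicate 1 (camera adjusted p = 0.0403). Abca1, the cholesterol exporter, rose with a log2 change of 1.86 ± 0.30. Cell cycle genes had a median log2 change of 0.99 (camera adjusted p = 9.06e-05, adjusted p = 0.405 by estimated correlation). Of 24 members 6 rose and 18 did not pass (6 rose adjusted over the list alone).

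Markers of tissue at the brain surfaces differed between MCAO libraries. Of 12 choroid plexus markers, 3 rose and 9 did not pass (7 rose adjusted over the list alone), at a median log2 change of 2.66 (camera adjusted p = 0.0326, adjusted p = 0.535 by estimated correlation). The choroid plexus medians were 4.09 in replicate 1, 0.25 in replicate 2 and 0.07 in the unnumbered library. Without MCAO replicate 1 the median of that list was 0.03 (camera adjusted p = 0.435), and without sham LN replicate 2 the camera adjusted p was 0.0585. F5, coagulation factor V, rose (log2 change 5.14 ± 0.98, edgeR adjusted p = 0.00655), and so did Ttr, the thyroid hormone carrier made by choroid plexus (log2 change 7.91 ± 2.17, edgeR adjusted p = 0.0285). Ttr did not pass when MCAO replicate 1 and sham LN replicates 1, 2 and 3 were each left out (adjusted p = 0.501, 0.0753, 0.0955 and 0.0991). Ependymal markers had a median log2 change of -1.48 (camera adjusted p = 0.0878). Of 11 members 1 rose, 1 fell and 9 did not pass (1 rose and 2 fell adjusted over the list alone). The ependymal median was -2.73 without MCAO replicate 1 (camera adjusted p = 0.0127) and -2.06 without sham LN replicate 2 (camera adjusted p = 0.000323). Hydin, a protein of motile cilia, fell (log2 change -2.80 ± 0.53, edgeR adjusted p = 0.00674). Meningeal markers had a median log2 change of 0.12 (camera adjusted p = 0.688), and of 11 members 2 rose and 9 did not pass (2 rose adjusted over the list alone). Of 6 skeletal muscle genes, 1 fell and 5 did not pass (1 fell adjusted over the list alone), at a median log2 change of -0.37 (camera adjusted p = 0.361). Among lists too short to test, red cell genes had medians of 0.75, 1.19 and 0.56 in replicates 1 and 2 and the unnumbered library. Pituitary hormone genes had -1.34, -2.21 and -1.40.

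**Figure D1:**
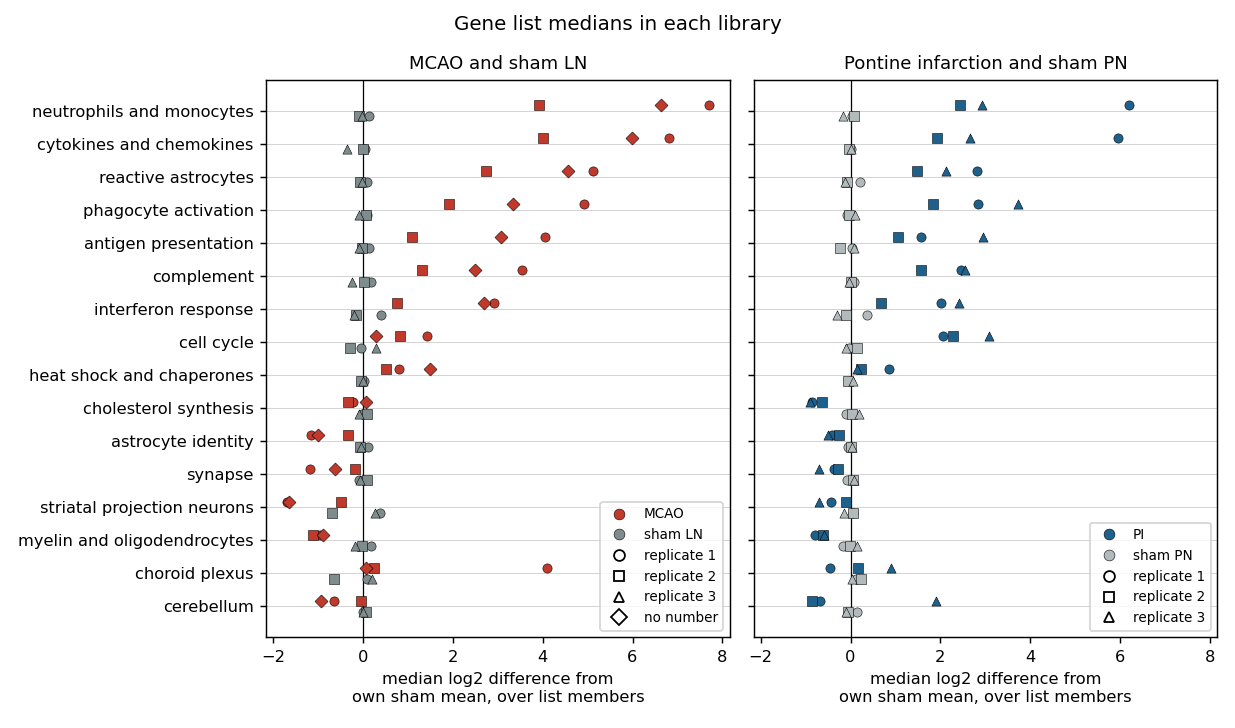
Each point is 1 library, at the median over the members of a gene list of its log2 difference from the mean of its own sham group (stroke libraries coloured, shams grey, marker shape by replicate). MCAO replicate 2 lies at 1.92 for phagocyte activation, MCAO replicate 1 stands apart in choroid plexus markers at 4.09, and pontine infarction replicate 3 in cerebellar markers at 1.90.

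Pontine infarction was compared with sham PN in the same way. Itgax stood at 16.1 ± 4.77 CPM against 0.193 ± 0.0296 in shams (log2 change 6.35 ± 0.43, edgeR adjusted p = 0.000109), and Clec7a at 21.0 ± 18.8 CPM against 0.135 ± 0.133 in shams (log2 change 7.18 ± 0.78, edgeR adjusted p = 0.00406). Aspg rose in the same comparison (log2 change 2.87 ± 0.36, edgeR adjusted p = 0.00508), and Gfap rose from 1519.8 ± 100.4 CPM to 5393 ± 1490.3 CPM (log2 change 1.83 ± 0.21, edgeR adjusted p = 0.00508). Mki67, a protein of dividing cells, stood at 20.4 ± 5.57 CPM against 1.502 ± 0.433 in shams (log2 change 3.76 ± 0.50, edgeR adjusted p = 0.00537). Lss, the enzyme that closes the sterol rings in cholesterol synthesis, fell from 99.1 ± 19.9 CPM to 36.0 ± 6.99 CPM (log2 change -1.46 ± 0.19, edgeR adjusted p = 0.00537). Among the last 3 genes, the call was lost for all 3 without sham PN replicate 3 (adjusted p = 0.0511 to 0.063).

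After pontine infarction 694 genes changed, 4.08% of those tested, of which 546 rose and 148 fell (edgeR quasi-likelihood test). At least 2-fold changes numbered 526 upward and 54 downward. The count was 431, 965 and 310 without infarction replicates 1 to 3 and 182, 52 and 6 without sham PN replicates 1 to 3. Of 85 genes named by the rule that passed, 3 kept an adjusted p under 0.05 whichever of the 6 libraries was left out, and these were Itgax, Clec7a and Aspg. The number of the 85 still past the threshold was 57 without pontine infarction replicate 1, 81 without replicate 2 and 55 without replicate 3, and it was 36, 18 and 3 without sham PN replicates 1, 2 and 3. DESeq2 called 1738 genes (1224 rose, 514 fell), limma voom 1968 (1068 rose, 900 fell), and edgeR with all 6 shams as the control 1512. By camera with its preset correlation 29 of 41 lists passed, 21 upward and 8 downward, and by fry 15, and in 28 of the 29 all 3 infarction libraries had medians on the list's side. With an estimated correlation none did by camera, and the adjusted p-values of the 29 lists lay between 0.079 and 0.603.

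Genes of dividing cells rose after pontine infarction. Of 24 cell cycle genes, 22 rose and 2 did not pass (24 rose adjusted over the list alone), at a median log2 change of 2.59 (camera adjusted p = 2e-37, adjusted p = 0.079 by estimated correlation). Mcm3 rose with a log2 change of 2.63 ± 0.32, and Kif11, a motor of the mitotic spindle, with 2.45 ± 0.33 (edgeR adjusted p = 0.00508 and 0.00537). The call was lost for both without sham PN replicate 3 (adjusted p = 0.0511 to 0.0626). The cell cycle medians were 2.06, 2.29 and 3.08 in replicates 1 to 3. Cholesterol synthesis genes had a median log2 change of -0.84 (camera adjusted p = 2.53e-18, adjusted p = 0.079 by estimated correlation). Of 19 members 11 fell and 8 did not pass (19 fell adjusted over the list alone). Fdft1, squalene synthase, and Cyp51, a sterol demethylase, fell with log2 changes of -1.001 ± 0.13 and -0.87 ± 0.15 (edgeR adjusted p = 0.00537 and 0.0135). The threshold was missed by Cyp51 without sham PN replicate 2 (adjusted p = 0.0728) and both without sham PN replicate 3 (adjusted p = 0.0511 to 0.0731). Sterol efflux genes had a median log2 change of 0.60 (camera adjusted p = 0.000238, adjusted p = 0.268 by estimated correlation), and of 14 members 2 rose and 12 did not pass (5 rose adjusted over the list alone). Abca1 rose with a log2 change of 1.69 ± 0.30. Abca1 did not pass when sham PN replicates 1, 2 and 3 were each left out (adjusted p = 0.0569, 0.0749 and 0.0955).

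Oligodendrocyte lists passed downward by camera after pontine infarction, with few members past the threshold. Of 17 myelin and oligodendrocyte genes, 4 fell and 13 did not pass (11 fell adjusted over the list alone), at a median log2 change of -0.70 (camera adjusted p = 9.42e-10, adjusted p = 0.0895 by estimated correlation). Fa2h and Ugt8 fell with log2 changes of -1.05 ± 0.18 and -0.81 ± 0.16. Mbp stood at 20706 ± 1406 CPM against 33386 ± 4855 in shams and did not pass (log2 change -0.69 ± 0.24, edgeR adjusted p = 0.126). Oligodendrocyte precursor genes had a median log2 change of -0.42 (camera adjusted p = 0.00179, adjusted p = 0.184 by estimated correlation). Of 16 members 2 fell and 14 did not pass (4 fell adjusted over the list alone). Enpp6, an enzyme of newly forming oligodendrocytes, fell with a log2 change of -1.11 ± 0.25. Of Fa2h, Ugt8 and Enpp6, calls were lost for Enpp6 without infarction replicate 1 (adjusted p = 0.0542), Enpp6 and Ugt8 without infarction replicate 3 (adjusted p = 0.0591 to 0.0876), Enpp6 and Ugt8 without sham PN replicate 1 (adjusted p = 0.0665 to 0.103), all 3 without sham PN replicate 2 (adjusted p = 0.0654 to 0.114) and all 3 without sham PN replicate 3 (adjusted p = 0.077 to 0.116).

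Phagocyte lists passed upward by camera after pontine infarction. Of 23 phagocyte activation genes, 14 rose and 9 did not pass (19 rose adjusted over the list alone), at a median log2 change of 2.78 (camera adjusted p = 5.92e-29, adjusted p = 0.0895 by estimated correlation). Gpnmb, a glycoprotein of lipid-laden macrophages, stood at 749 ± 731 CPM against 8.05 ± 0.950 in shams (log2 change 6.54 ± 0.75, edgeR adjusted p = 0.00508), and Spp1 at 910.3 ± 658 CPM against 121 ± 13.1 in shams (log2 change 2.91 ± 0.61, edgeR adjusted p = 0.0251). Cd68 rose with a log2 change of 5.31 ± 0.98. Markers of resting microglia had a median log2 change of 0.88 (camera adjusted p = 0.000269, adjusted p = 0.253 by estimated correlation). Of 14 members 4 rose and 10 did not pass (4 rose adjusted over the list alone). Gpr84 and Csf1r, a survival receptor of microglia, rose with log2 changes of 3.42 ± 0.45 and 1.44 ± 0.35, and Aif1 with 2.21 ± 0.43. This list, which holds Gpr84 of activated cells, rose in 2 of 3 libraries (medians -0.37, 0.53 and 1.254 in replicates 1 to 3). Complement genes had a median log2 change of 2.49 (camera adjusted p = 1.07e-19, adjusted p = 0.079 by estimated correlation), and of 17 members 11 rose and 6 did not pass (14 rose adjusted over the list alone). C1qc, a chain of the first complement component, rose with a log2 change of 2.51 ± 0.36 and Itgam with 3.54 ± 0.44. Of 8 lymphocyte markers, 2 rose and 6 did not pass (4 rose adjusted over the list alone), at a median log2 change of 2.43 (camera adjusted p = 5.22e-05, adjusted p = 0.161 by estimated correlation). Cd8a, the co-receptor of killer T cells, had 2 counts over the shams and 2365 over the infarction libraries (1008-fold, 95% counting interval 279 to 8327). Its levels in replicates 1 to 3 were 13.2, 2.90 and 73.2 CPM, beside 0.465, 0.0468 and 0.449 for the T cell gene Cd3e. With 1 library left out the Cd8a log2 change ran from 8.05 to 12.6. Scimp, an adaptor protein, had 445 counts and 0 over the shams, so it was at least 126-fold higher. Among the 10 genes called here, calls were lost for 3 of them without infarction replicate 3 (adjusted p = 0.0532 to 0.097), 5 of them without sham PN replicate 1 (adjusted p = 0.0549 to 0.123), 6 of them without sham PN replicate 2 (adjusted p = 0.0609 to 0.152) and all 10 without sham PN replicate 3 (adjusted p = 0.0511 to 0.145).

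Cytokine and leukocyte lists passed upward by camera too. Of 23 cytokine and chemokine genes, 9 rose and 14 did not pass (21 rose adjusted over the list alone), at a median log2 change of 5.04 (camera adjusted p = 7.66e-17, adjusted p = 0.181 by estimated correlation). With members at 0 counts set to their bound the median of this list was 4.77. Ccl6, a chemokine of macrophages, rose with a log2 change of 3.36 ± 0.52. Neutrophil and monocyte markers had a median log2 change of 5.23 (camera adjusted p = 8.8e-11, adjusted p = 0.184 by estimated correlation). Of 12 members 7 rose and 5 did not pass (10 rose adjusted over the list alone). Csf3r rose with a log2 change of 3.54 ± 0.61. The medians of neutrophil and monocyte markers were 6.20, 2.43 and 2.92 in replicates 1 to 3. Hba1 and Hba2 summed to 91.7 ± 56.7 CPM after pontine infarction and 22.4 ± 1.86 CPM in sham PN. Interferon-stimulated genes had a median log2 change of 2.32 (camera adjusted p = 1.26e-15, adjusted p = 0.186 by estimated correlation), and of 24 members 4 rose and 20 did not pass (22 rose adjusted over the list alone). Mx1, an interferon-induced antiviral protein, rose with a log2 change of 4.36 ± 0.81. Of 18 antigen presentation genes, 4 rose and 14 did not pass (13 rose adjusted over the list alone), at a median log2 change of 2.47 (camera adjusted p = 1.79e-11, adjusted p = 0.184 by estimated correlation). Ciita, the master regulator of MHC class II, rose with a log2 change of 3.91 ± 0.98. Cell death and p53 target genes had a median log2 change of 1.30 (camera adjusted p = 2.11e-12, adjusted p = 0.184 by estimated correlation). Of 23 members 8 rose and 15 did not pass (11 rose adjusted over the list alone). Casp8, the initiator caspase of death receptors, rose with a log2 change of 2.04 ± 0.31. Of Ccl6, Csf3r, Mx1, Ciita and Casp8, calls were lost for Ciita without infarction replicate 1 (adjusted p = 0.1), Ciita without infarction replicate 3 (adjusted p = 0.134), 3 of them without sham PN replicate 1 (adjusted p = 0.0548 to 0.127), 4 of them without sham PN replicate 2 (adjusted p = 0.0654 to 0.182) and all 5 without sham PN replicate 3 (adjusted p = 0.0626 to 0.191).

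Astrocyte, vessel and matrix lists gave mixed results. Of 22 reactive astrocyte genes, 11 rose and 11 did not pass (18 rose adjusted over the list alone), at a median log2 change of 2.57 (camera adjusted p = 5.5e-20, adjusted p = 0.0895 by estimated correlation). Socs3, a brake on cytokine signals, rose with a log2 change of 5.35 ± 0.90. General astrocyte markers had a median log2 change of -0.34 (camera adjusted p = 0.031, adjusted p = 0.603 by estimated correlation). Of 18 members 1 rose, 1 fell and 16 did not pass (1 rose and 2 fell adjusted over the list alone). Fgfr3, a growth factor receptor of astrocytes, fell (-0.75 ± 0.15), and Glul, glutamine synthetase, rose (0.63 ± 0.15). The camera adjusted p of that list was 0.0523 without pontine infarction replicate 1 and 0.0824 without replicate 3. Vessel activation and sprouting genes had a median log2 change of 1.51 (camera adjusted p = 0.0022, adjusted p = 0.378 by estimated correlation), and of 17 members 3 rose and 14 did not pass (8 rose adjusted over the list alone). Endothelial and barrier genes had a median log2 change of -0.07 (camera adjusted p = 0.772), and 0 of 20 passed, also when adjusted over the list alone. Cldn5 stood at 144 ± 52.1 CPM against 162 ± 24.96 in shams (edgeR adjusted p = 0.79). Mural cell markers had a median log2 change of -0.03 (camera adjusted p = 0.767). Of 15 members 1 rose and 14 did not pass (1 rose adjusted over the list alone). The sign of this median turned with DESeq2 size factors, and the mean log2 change was 0.17. Of 22 matrix and fibroblast genes, 3 rose and 19 did not pass (8 rose adjusted over the list alone), at a median log2 change of 0.95 (camera adjusted p = 1.89e-06, adjusted p = 0.241 by estimated correlation). Mmp14 rose with a log2 change of 2.22 ± 0.51. Axon growth inhibitor genes had a median log2 change of -0.51 (camera adjusted p = 0.0052, adjusted p = 0.318 by estimated correlation), and 0 of 20 passed, also when adjusted over the list alone. Mag, a myelin protein that stops axon growth, stood at 943 ± 19.1 CPM against 1473 ± 366 in shams (edgeR adjusted p = 0.129). Of Socs3, Fgfr3, Glul and Mmp14, the threshold was missed by 3 of them without infarction replicate 1 (adjusted p = 0.0714 to 0.113), Glul and Mmp14 without infarction replicate 3 (adjusted p = 0.0697 to 0.102), Glul and Mmp14 without sham PN replicate 1 (adjusted p = 0.104 to 0.11), all 4 without sham PN replicate 2 (adjusted p = 0.0777 to 0.147) and all 4 without sham PN replicate 3 (adjusted p = 0.0931 to 0.158).

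Of 5 stress lists, 4 passed upward by camera after pontine infarction, and these did not pass by fry (adjusted p = 0.0652 to 0.152). Of 17 heat shock and chaperone genes, 3 rose and 14 did not pass (4 rose adjusted over the list alone), at a median log2 change of 0.42 (camera adjusted p = 1.18e-05, adjusted p = 0.253 by estimated correlation). Hspb1 rose with a log2 change of 4.12 ± 0.64. Immediate early genes had a median log2 change of 0.57 (camera adjusted p = 0.00101, adjusted p = 0.348 by estimated correlation). Of 20 members 3 rose and 17 did not pass (4 rose adjusted over the list alone). Atf3 rose with a log2 change of 3.89 ± 0.68, and Fos stood at 29.3 ± 13.4 CPM against 15.8 ± 0.723 in shams without passing (edgeR adjusted p = 0.458). Regeneration-associated genes had a median log2 change of 0.64 (camera adjusted p = 0.000908, adjusted p = 0.241 by estimated correlation), and of 22 members 4 rose and 18 did not pass (5 rose adjusted over the list alone). Tubb6 rose with a log2 change of 3.11 ± 0.45. Of 21 hypoxia and glycolysis genes, 2 rose and 19 did not pass (3 rose adjusted over the list alone), at a median log2 change of -0.09 (camera adjusted p = 0.483). The mean of this list was 0.32 and camera gave an upward direction, against the sign of the median. Hk2 rose with a log2 change of 1.73 ± 0.37. Unfolded protein response genes had a median log2 change of 0.55 (camera adjusted p = 3.69e-05, adjusted p = 0.321 by estimated correlation). Of 20 members 4 rose and 16 did not pass (5 rose adjusted over the list alone). Pdia4 rose with a log2 change of 0.75 ± 0.16. Of Hspb1, Atf3, Tubb6, Hk2 and Pdia4, the threshold was missed by Hk2 and Pdia4 without infarction replicate 1 (adjusted p = 0.0516 to 0.0772), Hk2 and Pdia4 without infarction replicate 3 (adjusted p = 0.0532 to 0.0706), 3 of them without sham PN replicate 1 (adjusted p = 0.0548 to 0.0891), all 5 without sham PN replicate 2 (adjusted p = 0.0575 to 0.101) and all 5 without sham PN replicate 3 (adjusted p = 0.0723 to 0.137).

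Redox and energy lists moved little. Of 20 iron handling genes, 2 rose and 18 did not pass (3 rose adjusted over the list alone), at a median log2 change of 0.36 (camera adjusted p = 0.00773, adjusted p = 0.37 by estimated correlation). Hmox1 stood at 105 ± 71.2 CPM against 11.2 ± 2.07 in shams (log2 change 3.23 ± 0.62, edgeR adjusted p = 0.0187). Oxidative stress genes had a median log2 change of 0.29 (camera adjusted p = 0.0215, adjusted p = 0.378 by estimated correlation). Of 18 members 3 rose and 15 did not pass (4 rose adjusted over the list alone). Without pontine infarction replicate 1 this list had a camera adjusted p of 0.057. Mt2A, a metal-binding metallothionein, rose (log2 change 4.30 ± 0.93, edgeR adjusted p = 0.0273). Of Hmox1 and Mt2A, the call was lost by Mt2A without infarction replicate 1 (adjusted p = 0.0681), Hmox1 without infarction replicate 3 (adjusted p = 0.0515), both without sham PN replicate 1 (adjusted p = 0.074 to 0.0844), both without sham PN replicate 2 (adjusted p = 0.103 to 0.132) and both without sham PN replicate 3 (adjusted p = 0.102 to 0.146). Nuclear-encoded respiratory chain genes had a median log2 change of -0.22 (camera adjusted p = 0.00374, adjusted p = 0.386 by estimated correlation), and 0 of 23 passed, also when adjusted over the list alone. Mitochondrially encoded genes had a median log2 change of -0.20 (camera adjusted p = 0.192), and 0 of 13 passed, also when adjusted over the list alone. The mitochondrial list had a camera adjusted p of 0.00264 without pontine infarction replicate 1.

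Neuronal lists had small medians after pontine infarction. Of 21 synaptic genes, 1 fell and 20 did not pass (1 fell adjusted over the list alone), at a median log2 change of -0.49 (camera adjusted p = 0.000269, adjusted p = 0.379 by estimated correlation). Snap25 stood at 696 ± 197 CPM against 1075 ± 149 in shams (edgeR adjusted p = 0.133). Excitatory neuron markers had a median log2 change of -0.29 (camera adjusted p = 0.16), and 0 of 18 passed, also when adjusted over the list alone. Slc17a7 stood at 132 ± 166 CPM against 329.6 ± 106 in shams (edgeR adjusted p = 0.353). Without pontine infarction replicate 3 the camera adjusted p of that list was 0.0135. Inhibitory neuron markers had a median log2 change of -0.29 (camera adjusted p = 0.272), and of 15 members 1 fell and 14 did not pass (1 fell adjusted over the list alone). Striatal projection neuron markers had a median log2 change of -0.31 (camera adjusted p = 0.21), and 0 of 15 passed, also when adjusted over the list alone. Telencephalon genes had a median log2 change of -0.28 (camera adjusted p = 0.374), and 0 of 13 passed, also when adjusted over the list alone. For telencephalon genes the camera adjusted p was 0.0425 without sham PN replicate 3. Of 22 hindbrain genes, 1 fell and 21 did not pass (1 fell adjusted over the list alone), at a median log2 change of -0.49 (camera adjusted p = 0.0078, adjusted p = 0.184 by estimated correlation). That camera adjusted p was 0.0992 without pontine infarction replicate 2. Hoxb3, a positional gene of the hindbrain, fell (log2 change -2.25 ± 0.39, edgeR adjusted p = 0.0246). Hoxb3 did not pass when pontine infarction replicate 1 and sham PN replicates 1, 2 and 3 were each left out (adjusted p = 0.0553, 0.074, 0.11 and 0.126).

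Cerebellar markers set pontine infarction replicate 3 apart. Cerebellar markers had a median log2 change of 0.79 (camera adjusted p = 0.581), and 0 of 16 passed, also when adjusted over the list alone. The medians were -0.69, -0.85 and 1.90 in replicates 1 to 3. Without replicate 3 the list median was -0.90 (camera adjusted p = 9.52e-05), and without replicate 1 it was 1.38 (camera adjusted p = 0.014). Choroid plexus markers had a median log2 change of 0.69 (camera adjusted p = 0.925), and 0 of 12 passed (1 fell adjusted over the list alone). Ependymal markers had a median log2 change of 1.07 (camera adjusted p = 0.00452, adjusted p = 0.378 by estimated correlation), and 0 of 11 passed, also when adjusted over the list alone. Meningeal markers had a median log2 change of 0.39 (camera adjusted p = 0.625), and 0 of 11 passed, also when adjusted over the list alone. Without pontine infarction replicate 1 the meningeal median was 0.74 (camera adjusted p = 0.0302). Skeletal muscle genes had a median log2 change of -0.69 (camera adjusted p = 0.0945), and 0 of 6 passed (3 fell adjusted over the list alone). Red cell genes, too few for a test, had medians of 2.19, -0.06 and 1.99 in replicates 1 to 3. Pituitary hormone genes had -0.87, 0.49 and -0.15.

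**Figure D2:**
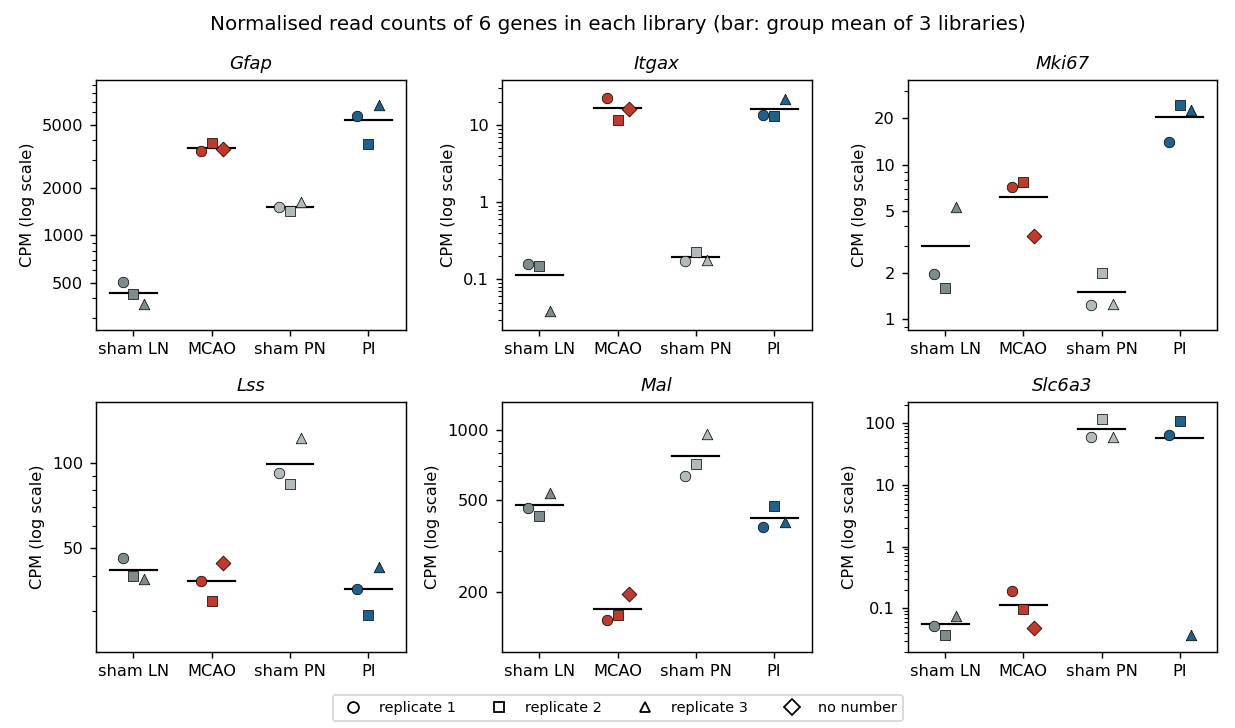
Normalised read counts (CPM, log scale) of 6 genes in each of the 12 libraries, with a bar at the mean of the 3 libraries of a group. Itgax was 16.9 CPM after MCAO and 16.1 CPM after pontine infarction, and the dopamine transporter gene Slc6a3 was 0.0374 CPM in pontine infarction replicate 3, 64.9 in replicate 1 and 108 in replicate 2.

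The responses to the 2 strokes were compared, using separate controls. In both strokes 445 genes changed in the same direction, 390 upward and 55 downward, where independent lists would share 68.4 and 8.98. Itgax, Clec7a, Aspg and Gfap are among those that rose, and Mal, Fa2h and Ugt8 among those that fell. In opposite directions 2 genes changed, with 51.7 expected: Crtac1 (log2 change 0.99 after MCAO and -1.05 after pontine infarction) and Vash2 (0.76 and -0.99), named after their values were seen. Of the 694 genes called after pontine infarction, 674 (97.1%) had the same sign after MCAO. Across the 17008 tested genes the log2 changes correlated with Pearson's r of 0.72 and Spearman's rho of 0.58, and genes are not independent replicates. The shared count was 1055 without MCAO replicate 2. It was 236, 259 and 244 without sham LN replicates 1, 2 and 3, 251 and 225 without pontine infarction replicates 1 and 3, and 135, 37 and 6 without sham PN replicates 1, 2 and 3.

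The responses were compared as MCAO against sham LN minus pontine infarction against sham PN, which confounds stroke with region. By edgeR 0 genes passed, with 1826 at an unadjusted p under 0.05 and a smallest adjusted p of 0.100. DESeq2 called 238 genes and limma voom 259. Without MCAO replicate 2 the edgeR count was 970, and without the unnumbered MCAO library it was 1. By camera with the preset correlation 18 of 41 lists differed, a test added after the gene counts were seen. Reactive astrocyte genes and cytokine genes had higher changes after MCAO, by median log2 differences of 2.19 and 2.46 (camera adjusted p = 4.06e-10 and 1.89e-05, and adjusted p = 0.364 and 0.51 with an estimated correlation). Cell cycle genes had lower changes after MCAO, at -1.64, and cholesterol synthesis genes higher ones, at 0.59 (camera adjusted p = 3.39e-15 and 2.36e-09, and 0.364 for each by estimated correlation). Adjusted over the list alone 13 cell cycle genes had lower changes after MCAO, against 0 over all genes. With an estimated correlation 0 lists passed, and by fry 0 did, with a smallest adjusted p of 0.0931.

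**Figure D3:**
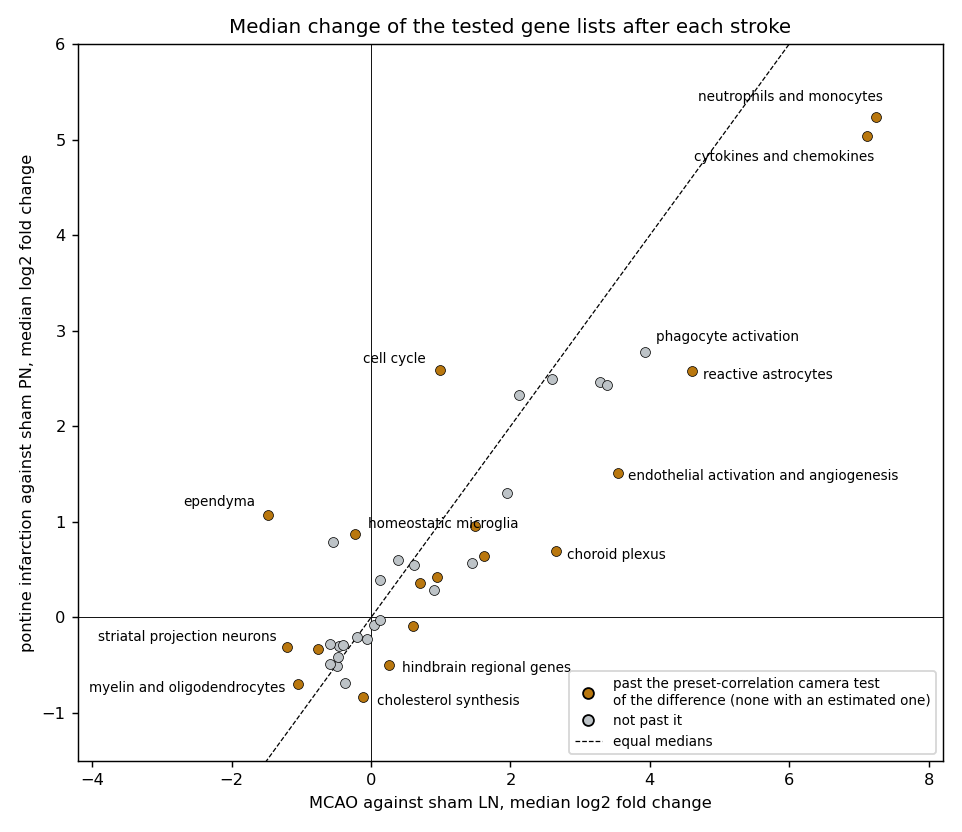
Median log2 fold change of each tested gene list after MCAO (horizontal) and after pontine infarction (vertical), 1 point per list, with the dashed line marking equal medians. Cell cycle genes lie at 0.99 and 2.59 and reactive astrocyte genes at 4.61 and 2.57; coloured points passed camera's preset-correlation test of the difference.

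The sham groups were compared to show how far the controls of the strokes differ. Tbr1, a transcription factor of cortical projection neurons, was at 63.1 ± 27.9 CPM against 0.186 ± 0.130 in sham PN (log2 difference 8.40 ± 0.78, edgeR adjusted p = 3.8e-05). Drd1, a dopamine receptor of striatal neurons, was at 211 ± 78.0 CPM against 3.29 ± 0.608 in sham PN (log2 difference 6.01 ± 0.43, edgeR adjusted p = 8.89e-06). Hoxb3 and En2, genes of the hindbrain and of the midbrain to cerebellum, had 0 counts over the sham LN libraries and 7.13 ± 0.701 and 13.5 ± 2.17 CPM in sham PN, so they were lower in sham LN by at least 218-fold and at least 413-fold. Th, the rate-limiting enzyme of dopamine synthesis, was at 1.94 ± 0.401 CPM against 139 ± 46.5 in sham PN, and Slc6a3, the dopamine transporter, at 0.0554 ± 0.0199 CPM against 79.8 ± 33.6 in sham PN (edgeR adjusted p = 1.46e-05 and 0.00235).

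Between the shams 3625 genes differed, 21.3% of those tested, of which 1702 were higher and 1923 lower in sham LN (edgeR quasi-likelihood test). Differences of at least 2-fold numbered 1125 and 1120. With DESeq2 size factors 1902 were higher and 1689 lower, and by DESeq2 2296 and 2216. Fitted on the 6 sham libraries alone, the count was 6365, with limma voom 7600, and 2334 without sham LN replicate 3. Of 93 named genes that passed, 72 stayed past the threshold whichever sham library was left out, Tbr1, Drd1, Hoxb3, En2, Th and Slc6a3 among them. Slc6a3 did not pass by limma voom. The list tests of this comparison were added after the gene counts were seen, and 12 of 41 lists passed by camera with the preset correlation, 7 higher and 5 lower in sham LN, by fry 12, and 2 with an estimated correlation.

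Regional and neuronal lists except cerebellar markers (camera adjusted p = 0.0509) separated the shams. Of 13 telencephalon genes, 12 were higher and 1 did not pass (13 were higher adjusted over the list alone), at a median log2 difference of 6.36 (camera adjusted p = 4.88e-28, adjusted p = 0.0126 by estimated correlation). Hindbrain genes had a median log2 difference of -8.35 (camera adjusted p = 4.87e-25, adjusted p = 0.000868 by estimated correlation). Of 22 members 20 were lower and 2 did not pass (21 were lower adjusted over the list alone). With members at 0 counts set to their bound this median was -6.25. Striatal projection neuron markers had a median log2 difference of 3.74 (camera adjusted p = 6.52e-31, adjusted p = 0.0523 by estimated correlation), and of 15 members 15 were higher (15 were higher adjusted over the list alone). Of 18 excitatory neuron markers, 13 were higher and 5 did not pass (17 were higher adjusted over the list alone), at a median log2 difference of 1.92 (camera adjusted p = 3.51e-20, adjusted p = 0.0523 by estimated correlation). Inhibitory neuron markers had a median log2 difference of 0.92 (camera adjusted p = 0.0152, adjusted p = 0.191 by estimated correlation). Of 15 members 8 were higher, 2 were lower and 5 did not pass (8 were higher and 2 were lower adjusted over the list alone). Synaptic genes had a median log2 difference of 1.38 (camera adjusted p = 5.62e-11, adjusted p = 0.308 by estimated correlation), and of 21 members 13 were higher, 1 was lower and 7 did not pass (13 were higher and 1 was lower adjusted over the list alone). Of 20 immediate early genes, 8 were higher and 12 did not pass (9 were higher adjusted over the list alone), at a median log2 difference of 1.79 (camera adjusted p = 8.72e-06, adjusted p = 0.333 by estimated correlation).

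Oligodendrocyte lists stood lower in sham LN. Of 17 myelin and oligodendrocyte genes, 15 were lower and 2 did not pass (16 were lower adjusted over the list alone), at a median log2 difference of -1.18 (camera adjusted p = 4.43e-11, adjusted p = 0.0554 by estimated correlation). Mbp was at 12009 ± 2644 CPM against 33386 ± 4855 in sham PN (edgeR adjusted p = 0.00134). Oligodendrocyte precursor genes had a median log2 difference of -0.86 (camera adjusted p = 0.0197, adjusted p = 0.333 by estimated correlation). Of 16 members 7 were lower and 9 did not pass (7 were lower adjusted over the list alone). Cholesterol synthesis genes had a median log2 difference of -0.85 (camera adjusted p = 2.85e-08, adjusted p = 0.191 by estimated correlation), and of 19 members 14 were lower and 5 did not pass (17 were lower adjusted over the list alone). Of 11 meningeal markers, 4 were lower and 7 did not pass (4 were lower adjusted over the list alone), at a median log2 difference of -1.42 (camera adjusted p = 0.0206, adjusted p = 0.837 by estimated correlation). Skeletal muscle genes had a median log2 difference of 1.01 (camera adjusted p = 0.0351, adjusted p = 0.191 by estimated correlation). Of 6 members 3 were higher and 3 did not pass (3 were higher adjusted over the list alone). Gfap was lower in sham LN (-1.81 ± 0.21, edgeR adjusted p = 0.000155) and so was Spp1 (-7.39 ± 0.80, edgeR adjusted p = 8.88e-05). Aif1, Cd68, Hmox1, Fos, Snap25, Slc17a7 and Cldn5 did not pass, with log2 differences of -0.01, -0.44, -0.95, 0.01, 0.36, 1.77 and -0.22.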

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

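The list tests of the difference between the strokes were chosen after the gene counts were seen, as were the tests of sham label, depth, blood and myelinating cells, and the rule for uninjured tissue was made stricter after its value was seen. The 18 lists given here differed between the responses in a test of the difference itself, by camera with the preset correlation. Their median log2 differences, MCAO minus pontine infarction, were 2.46 for cytokines, 2.19 for choroid plexus, 2.19 for reactive astrocytes, 2.12 for neutrophils and monocytes, 1.46 for hindbrain genes, 1.37 for vessel activation, 1.16 for regeneration, 0.76 for iron handling, 0.71 for hypoxia, 0.59 for cholesterol synthesis, 0.52 for heat shock and 0.29 for matrix. They were -0.29 for myelin, -0.44 for astrocyte identity, -0.82 for striatal neurons, -1.08 for resting microglia, -1.64 for cell cycle and -2.74 for ependyma. With an estimated correlation the adjusted p-values ran from 0.364 to 0.721, and by edgeR 0 genes differed. Of these, 4 lost their call without single libraries (camera adjusted p in brackets): choroid plexus without MCAO replicate 1 (0.303), myelin without MCAO replicate 2 (0.0727), iron handling without MCAO replicate 1 (0.505), pontine infarction replicate 2 (0.130), sham LN replicate 3 (0.0599) or sham PN replicate 3 (0.0516), and matrix without MCAO replicate 1 (0.570), pontine infarction replicates 1 and 2, sham LN replicates 1 and 3 or sham PN replicates 1 and 2 (0.0657 to 0.276).

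MCAO replicate 2 lay between the shams and the other MCAO libraries. Its position on that path was 0.271 for phagocyte activation, 0.180 for cytokines, 0.211 for reactive astrocytes and 1.02 for myelin. Bootstrap 95% intervals over members did not overlap in 3 of 6 pairs, each with myelin. Only myelin argues against plain dilution with uninjured tissue. A sham library under an MCAO label is set against its phagocyte median of 1.92, where the 6 shams lie between -0.09 and 0.09. Lower depth is set against its 20.4 M counts, beside 19.96 M and 21.5 M. A smaller injury or another dissected part stays open, untested.

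Neutrophil and monocyte markers passed upward after both strokes by camera with the preset correlation, but not with an estimated one (adjusted p = 0.214 and 0.184), and 5 of 12 members did not pass after pontine infarction. Blood left in the vessels would raise globin as much, but the smaller gap between list median and globin change was 3.20 (bootstrap 95% interval over members 1.83 to 5.24). The list medians were 7.24 and 5.23 and the globin changes 0.43 and 2.04. More white cells in the blood itself stays open.

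Cholesterol synthesis genes passed downward after pontine infarction by camera with the preset correlation, but not with an estimated one (adjusted p = 0.079), with 8 of 19 members not past the threshold, and had a median near 0 after MCAO. The difference passed by the preset correlation only (adjusted p = 0.364 with an estimated one, 0.0931 by fry). Fewer myelinating cells would lower them along with myelin genes, but after MCAO their median exceeded that of myelin by 0.93 (bootstrap 95% interval over members 0.55 to 1.13). After pontine infarction this difference was -0.14 (likewise -0.32 to 0.05), leaving the explanation open there. Cholesterol genes were lower in sham LN than sham PN (median -0.85), so unequal baselines stay open. With DESeq2 size factors the strokes differed by 0.51 (quartiles 0.44 to 0.83), which leaves a bias shared by both scalings open. Regional genes separated the shams, so stroke and region are confounded, and times were not given.

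Splits of the 6 libraries of a comparison number 10, too few for a share under 0.05. The real split gave 3163 genes for MCAO, 694 for pontine infarction and 3625 for the shams, and the highest other split 0 in each (1 of 10 splits as large). For lists the real split gave 28 after MCAO (2 of 10 as large, highest other 29) and 29 after pontine infarction (1 of 10, highest other 28). The other splits gave 7 to 29 and 14 to 28 lists, so the preset-correlation test calls lists under wrong groupings too. For genes changed the same way in both strokes 1 of 60 drawn splits (the real one, 445 genes, highest other 2) was as large, which excludes only an arbitrary grouping of both strokes at once. Wrong splits of a single stroke called 0 genes, so the sharing itself is not tested. For the difference, 60 of 60 splits gave as many genes as the real 0, which any split must, so this decides nothing. As many lists as 18 came from 42 of 60 (highest other 32), so chance is not excluded for the lists. The highest other gene count was 4688, from the split that exchanges stroke and sham in the pontine group and so adds the responses.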

How the results depend on the processing

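Leaving out the libraries numbered 2 of both strokes was chosen after seeing the data, because they lay nearest the shams. Genes are given for MCAO, pontine infarction, the difference, the shams and the shared set (3163, 694, 0, 3625 and 445). DESeq2 gave 4584, 1738, 238, 4512 and 1122 genes, with 3152 of the 3163 and 692 of the 694 among them. Limma voom gave 5390, 1968, 259, 7600 and 1141 (3018 and 671 among them). Without a filter 1 gene differed between the strokes. The compared libraries alone gave 1354 for MCAO and 6365 for the shams, where the spread is taken from 6 libraries. All 6 shams gave 1512 for pontine infarction, and a 2-fold minimum 2245 between the shams. Without both libraries numbered 2 the counts were 6176, 1991 and 596, with 1486 shared. With the replicate number as a block they were 130, 105, 0 and 6124, with 50 shared, and 88 named genes lost the threshold for MCAO and 53 for pontine infarction. The numbers were not taken to pair the samples, because not every pair exceeds r = 0.1: deviations correlated across genes with r of 0.104 and 0.0426 between MCAO and sham LN of the same number, 0.0483, 0.150 and 0.154 between pontine infarction and sham PN, 0.153, 0.0804 and 0.0435 between the shams, -0.141 to 0.0465 between different numbers and -0.0710 to 0.0905 for the unnumbered library. The 8 same-number values were positive, and in the last 2 comparisons every library correlated best with its own number, a hint from the data, not the design. By camera 0 lists passed with an estimated correlation in each of MCAO, pontine infarction and the difference, and by fry 15 for pontine infarction and 0 for the difference. The other counts stayed within 1.5 times, and the cause was not tested for these changes.

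Leaving out 1 library at a time, counts ran from 1136 to 6170 for MCAO, 6 to 965 for pontine infarction, 0 to 970 for the difference, 2334 to 2662 for the shams and 6 to 1055 for shared genes, and lists from 25 to 32, 28 to 30 and 17 to 27. The spread is pooled over the groups, also where an arm keeps 2 libraries. Among lists that passed with or without the library, medians that changed sign ran from -0.90 to 1.38 for cerebellum after pontine infarction, and in the difference from -1.45 to 0.77 for cerebellum, -0.63 to 3.13 for choroid plexus, -0.60 to 0.66 for complement, -0.075 to 0.85 for matrix and -0.014 to 0.88 for iron handling. The first pair turned without pontine infarction replicate 3 and the others without MCAO replicate 1. Lists that passed in neither fit also changed sign. Of the named genes' values over all settings, 1532 kept side and direction, 258 lost the threshold and 21 gained it for MCAO, against 1267, 331 and 18 for pontine infarction and 1541, 85 and 26 for the shams, and none of these changed sign. A further 3, 19 and 21 changed sign without passing in either fit. DESeq2 size factors move the median of all genes by -0.039 for MCAO and 0.033 for pontine infarction. In simulations a 2-fold change was called for 8.96% of genes in the difference, 31.3% for MCAO and 28.4% for pontine infarction.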

Other observations

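Pitx3, Slc18a2, Ddc, Nr4a2, Clic6 and Glra1 were chosen after their values were seen. Several dopamine neuron genes were low in pontine infarction replicate 3. Slc6a3 stood at 0.0374 CPM there, 64.9 and 108 in replicates 1 and 2, and 60.5, 119 and 60.3 in sham PN replicates 1 to 3. Pitx3 stood at 0.187 CPM against 2.74 and 5.10, Th at 57.7 against 119 and 197, Slc18a2 at 28.9 against 109.8 and 113, and Ddc at 36.1 against 96.0 and 105. Nr4a2 was not low, at 9.46 against 8.56 and 13.1. The median of cerebellar markers in that library was 1.90, and -0.69 and -0.85 in the others.

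Ttr stood at 1019 CPM in MCAO replicate 1, 0.691 in replicate 2 and 5.51 in the unnumbered library, and Clic6 at 38.5, 0.296 and 0.967. The glycine genes Slc6a5 and Glra1 stood at 17.1 and 11.5 CPM in MCAO replicate 1, 3.50 and 0.395 in replicate 2 and 21.6 and 8.80 in the unnumbered library. The Y-linked genes Kdm5d and Eif2s3y had 0 counts in all 12 libraries, and Ddx3y at most 24.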
